A study of Homo sapiens with 21 samples.

How the data were processed

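The series holds 21 samples of FaDu, an established cell line from a squamous cell carcinoma of the hypopharynx. IGF2BP3, an RNA-binding protein that reads m6A (N6-methyladenosine, a methyl mark on RNA), was knocked down under the names sh3-1 and sh3-2, taken here as 2 hairpins against the same gene. The controls are named shCtr and labelled as wild type with a blank treatment. Total RNA circRNA-seq was made from 9 libraries, 3 per group. MeRIP-seq, in which an antibody enriches m6A-marked RNA fragments and is compared with the input RNA, was made from 12 libraries, which are 6 pairs of IP and input from sh3-2 and shCtr. Per the labels' protocols, ribosomal RNA was depleted, libraries were made with a strand-specific kit, and paired reads of 150 bp were sequenced on a NovaSeq. No step that removes linear RNA is named there.

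Per the submitters' processing notes, cutadapt 1.9.3, STAR 2.5.1b, edgeR 3.16.5 and the human build hg19 were used, with no role or order given. The circRNA caller, its minimum number of reads, the peak caller and their settings are not given in the sources used here. The deposited circRNA sheets give, per the file headers, whole-number counts of back-splice junction reads for each circRNA and library, with no normalization. In the same sheets the authors give a log2 fold change and a mean log2 CPM (reads scaled to library size) for each circRNA, and a p-value with an adjusted p-value (FDR). The sheets also give a log2 CPM per library, and these 24 columns were not used. In the deposited m6A sheets the authors give each site a fold (a ratio of at least 1, with its direction in a separate column), a p-value and FDR. The authors' deposited score is the −log10 of that p-value, and the authors also give the length of the site in bases. The sheets do not state whether the m6A fold is corrected for input. Coordinates, strand, host gene, circBase ID and class (exonic, intronic, sense overlapping, antisense or intergenic) are those of the authors' deposited sheets in hg19. No reference genome was used.

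The sh3-1 sheets list 7021 circRNAs and the sh3-2 sheets 6648, 8714 in all and 4955 in both. Each circRNA had at least 2 reads in some library. Control counts were identical in the sheets of both comparisons, and circRNAs listed for 1 comparison had 0 control reads. A circRNA missing from a hairpin's sheets was therefore given 0 reads in that hairpin's libraries. This was checked by recomputing the authors' mean log2 CPM over 9 libraries, which differed by a median of 0.01 for circRNAs in both sheets and by at most 0.10 in any sheet. For shares and floors, library size was the sum of junction reads. In the edgeR fits it was the sum over the circRNAs that the filter kept. Their log2 fold changes are therefore relative to those circRNAs and not to all junction reads. The alternative of library totals used all junction reads. A count of 0 in a library of this depth allows a share of up to 0.0513% to 0.0795% of its junction reads (3 counts of the total). Intervals and floors cover counting error only, since PCR copies were not told apart. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

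Each hairpin was compared with the controls in a fit of its own 6 libraries, and sh3-2 with sh3-1 in a fit of all 9 over the circRNAs in both comparisons' sheets, by the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, TMM factors, filterByExpr with its defaults, two-sided). R 4.3.3, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. P-values were adjusted by Benjamini-Hochberg and a call is an FDR under 0.05. Lists of host genes with at least 5 tested circRNAs were tested with camera (preset correlation of 0.01, and again with an estimated one) and fry as an alternative. Values per library were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. The planned test of m6A assumed values per library. The m6A sheets hold none, so the planned fallback was used. The authors' folds and FDR are described, and each list's median log2 fold over circRNAs was set against circRNAs of other hosts in a two-sided permutation test of 100000 draws. The groups, tests, 12 host gene lists, named circRNAs and most alternatives were chosen before the data were examined, and those added later are said to be so.

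The count test was tested on simulated data with the means, library sizes and common dispersion of these libraries. For sh3-1 (33 circRNAs tested), 5.10% of circRNAs raised by 2-fold in the hairpin libraries, 81% of those raised by 4-fold and 100% of those raised by 8-fold were called. For sh3-2 (24 tested), the shares were 15.2%, 88% and 100%. Over the 20 runs at each fold, unchanged circRNAs were called 1, 2 and 11 times for sh3-1 and 2, 12 and 15 times for sh3-2. In another run 200 circRNAs among all were changed by 4-fold or 8-fold either way. Only 3 and 6 of them had enough reads to be tested, and all of these were called. Decreases were simulated only in that run, so the share of lowered circRNAs called at each fold is not known. Overlaps and correlations of the hairpins, which share their controls, are printed beside those of 9 simulated unchanged libraries, in which both hairpin groups share the simulated controls. Correlations are also printed beside hairpin libraries simulated against the 3 real controls, which was added after the data were seen.

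The circRNAs named in each comparison were to be the 10 with the largest fold each way among calls whose 3 knockdown values lie on one side of the controls. Where fewer passed, the list was filled by the smallest unadjusted p, which was the case throughout circRNA-seq. Also named were all circRNAs of HECTD2 and IGF2BP3, circRNAs lower in both datasets, and the 2 members of each host gene list with the smallest p each way. Some genes that the rule names are not reported here. CircRNAs and hosts named outside this rule are said to be chosen after their values were seen. The alternatives were DESeq2, RLE factors, library totals, no filter, a mean of at least 10 reads, a replicate block, 1 fit of all 9 libraries, looser thresholds, the authors' p-values and leaving out each library. Added after the data were seen were reads summed over a host gene and over library pairs, the authors' deposited p with a fold of at least 2, and no filter with looser thresholds, for the host gene lists, for both hairpins together and for the relation of circRNA and m6A. In host sums, 15 circRNAs with no host (0.0927% of reads) were left out. Reads summed over chromosomes were tested outside the plan.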

Results

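Circular RNAs of FaDu hypopharyngeal carcinoma cells were counted by back-splice junction reads in 3 control libraries (shCtr) and in 3 libraries of each of the IGF2BP3 hairpins sh3-1 and sh3-2. In all, 8714 circRNAs of 3809 host genes had reads, and 4879 (56.0%) carry a circBase ID in the authors' deposited table. Exonic circRNAs numbered 6093 (69.9%) and held 79.4% of the junction reads, sense overlapping ones 1529 (12.4% of reads) and intronic ones 1046 (7.89% of reads). The SPECC1 circRNA 17:20107646-20109225 had 92.3 ± 8.08 reads per control library (mean ± SD, n = 3), the GUSBP1 circRNA 5:21491430-21497305 had 45.7 ± 13.7 and the PLOD2 circRNA 3:145838899-145842016 had 44.3 ± 11.7. Most circRNAs were rare: 5404 (62.0%) had reads in 1 library only and 77 had reads in all 9.

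Libraries of sh3-2 held fewer junction reads, 3937 ± 205 against 5624 ± 170 in controls (30.0% fewer; exact two-sided permutation p = 0.1, the smallest possible with 3 against 3), and those of sh3-1 held 5534 ± 446 (exact p = 0.9). CircRNAs detected per library were 1968 ± 160 in controls, 1779 ± 130 with sh3-1 (exact p = 0.2) and 1575 ± 148 with sh3-2 (exact p = 0.1). Exonic circRNAs made up 80.0 ± 0.513% of control reads, 80.3 ± 1.76% with sh3-1 (exact p = 0.8) and 77.2 ± 1.29% with sh3-2 (exact p = 0.1). The intronic share was 6.82 ± 0.357%, 8.39 ± 1.33% (exact p = 0.2) and 8.80 ± 0.572% (exact p = 0.1). The sense overlapping share was 13.0 ± 0.237%, 10.9 ± 0.365% (exact p = 0.1) and 13.7 ± 0.916% (exact p = 0.3).

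A pair of libraries in each hairpin group held many circRNAs in common that no other library held. These were sh3-1 A and B with 360 and sh3-2 B and C with 197, and the other 34 pairs of libraries shared 10 to 87. Of the circRNAs found in either library of a pair, 35.0% and 27.9% were found in both, against 11.2% to 17.7% for other pairs. The heatmap of library pairs shows these numbers.

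**Figure D1:**
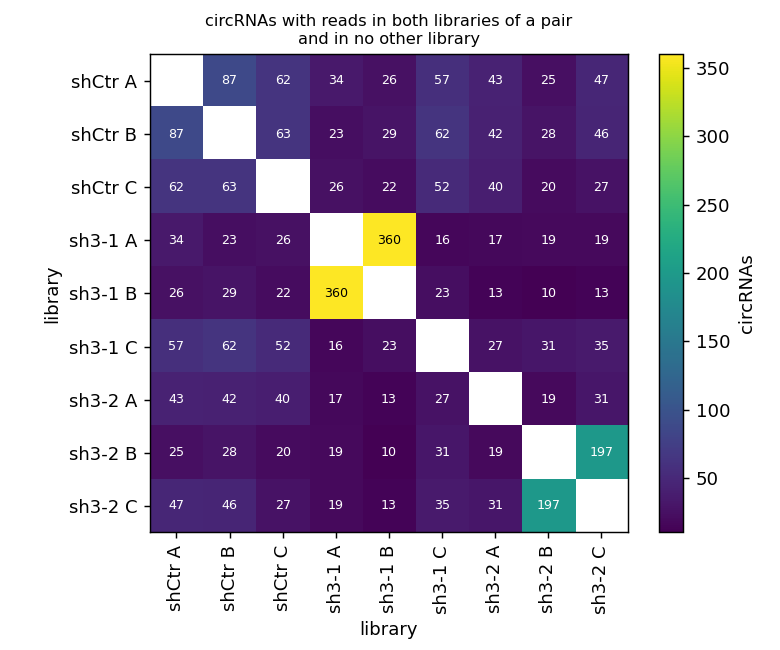
Number of circRNAs found in both libraries of a pair and in none of the other 7, for each pair of the 9 circRNA-seq libraries (3 each of shCtr, sh3-1 and sh3-2). Axes name the libraries and the colour gives the number of circRNAs.

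With the first hairpin no circRNA passed an FDR of 0.05 against controls. The largest differences by p were a SETD3 circRNA (14:99924616-99932150, hsa_circ_0000567; SETD3 is an actin histidine methyltransferase), with 17 ± 7 reads against 7 ± 4.36 in controls, and a MIB1 circRNA (18:19345733-19359646, hsa_circ_0000835; MIB1 is a ubiquitin ligase of Notch signalling), with 7 ± 4.58 against 13.7 ± 6.66. Their log2 fold changes by edgeR were 1.18 (SE 0.55) and −1.11 (SE 0.55), each with an adjusted p of 0.734. Circles of the nuclear export receptor XPO1 (2:61749746-61761038, log2 −0.94, SE 0.55) and of the protein kinase PRKD3 (2:37543380-37544322, log2 −0.90, SE 0.52) lay lower, and one of the lipid transfer protein ESYT2 (7:158552177-158557544, log2 0.79, SE 0.53) lay higher. For XPO1 all 3 sh3-1 libraries (7, 8 and 11 reads) lay below all 3 controls (12, 13 and 21). No other circRNA tested with sh3-1 was separated in this way. With 3 against 3 libraries such a separation gives an exact two-sided permutation p of only 0.1, so it is not read as an effect.

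Of the circRNAs with sh3-1, 33 had enough reads to be tested (10.9% of junction reads), 13 higher and 20 lower than in controls. EdgeR gave 0 calls, with 1 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 gave 0 calls with 1 at that level. Circles filled in by the smallest p were higher for ARHGAP5 (14:32559708-32586493, log2 0.69, and 14:32559708-32563592, log2 0.52), CSNK1G3 (0.56), MYH9 (0.59), ZBTB44 (0.45), KIAA0368 (0.34), RARS (0.29) and PLOD2 (0.23). Lower ones came from LINC01004 (−0.80), ELK4 (−0.57), CAMSAP1 (−0.57), GUSBP1 (−0.54), SEMA3C (−0.52), NFATC3 (−0.41) and ZKSCAN1 (−0.41). For GUSBP1 and ZKSCAN1 the sign turned when a certain library was left out. The abundant SPECC1 circle had a log2 of −0.09 (SE 0.18), and the rarer SMAD2 circle 18:45391430-45423180 (hsa_circ_0000847) one of −0.17 with a wider SE of 0.54. In the authors' deposited table, a p under 0.05 and a fold of at least 2 were given for 72 circRNAs (27 higher, 45 lower), and 0 had an FDR under 0.05 (smallest 0.512). In simulated data of this depth, 5.10% of tested circRNAs raised by 2-fold and 81% of those raised by 4-fold were called. The share called among lowered circRNAs was not simulated at each fold.

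With the second hairpin a circle of MYH9, the nonmuscle myosin heavy chain gene, stood apart most. The MYH9 circRNA 22:36716843-36723533 had 26.3 ± 5.51 reads against 14 ± 9.17 in controls, in smaller libraries (log2 1.30, SE 0.48, edgeR adjusted p 0.202). No circRNA passed an FDR of 0.05. A circle of MGA (15:41961026-41962156, log2 1.05, SE 0.77) also lay higher, and circles of KIAA0368 (9:114148657-114154104, 5 ± 3.61 reads against 13.3 ± 8.62) and FAM13B (log2 −0.52, SE 0.32; 9.67 ± 2.08 reads against 18.3 ± 7.09) lay lower.

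With sh3-2, 24 circRNAs were tested (9.40% of junction reads), 11 higher and 13 lower. EdgeR gave 0 calls, with 1 higher and 0 lower at an unadjusted p under 0.05, and DESeq2 gave 0 calls with 2 at that level. The other circles filled in by the smallest p were higher for CSNK1G3 (0.56), HIPK3 (0.44), FIRRE (0.42), SPECC1 (0.26), RARS (0.25), RNF13 (3:149563798-149639014, 0.22), PRKD3 (0.14) and RBM33 (0.09). Lower ones came from QSER1 (−0.85), FBXW7 (−0.60), ELK4 (−0.56), GUSBP1 (−0.44), MPP6 (−0.37), XPO1 (−0.29), LINC01004 (−0.17) and PLOD2 (−0.14). The signs of RARS, RNF13, PRKD3, RBM33, LINC01004 and PLOD2 depended on a single library, as each turned when a certain library was left out. In the authors' deposited table, a p under 0.05 and a fold of at least 2 were given for 45 circRNAs (23 higher, 22 lower), and 0 had an FDR under 0.05 (smallest 0.558). The share of circRNAs that were higher was 41.1% for exonic ones and 44.9% for others (Fisher's exact p = 0.00522 by sign over all circRNAs, and 0.406 with sh3-1). This test counts circRNAs as its units, and by library the exonic share with sh3-2 gave the exact permutation p of 0.1 above.

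The HECTD2 circRNA of the series title (10:93185038-93221941, hsa_circ_0007168), from the gene of a HECT-domain ubiquitin ligase, had 3, 2 and 7 reads in the controls and 0 in all 6 hairpin libraries. Set against a floor of 3 reads over a group, this is 3.94-fold lower with sh3-1 and 2.80-fold lower with sh3-2. The control reads were taken as exact, so these folds are not lower bounds. In the authors' deposited table its p was 0.0214 and 0.0339 with an FDR of 0.512 and 0.558. The RNF13 circRNA 3:149613260-149639014 (hsa_circ_0006801), from the gene of a RING ubiquitin ligase, had 5, 3 and 4 control reads and 0 elsewhere. The ZNF292 circRNA 6:87925621-87928449 (hsa_circ_0004058) had 6 ± 3 reads in controls, 0.667 ± 1.15 with sh3-1 and 0.333 ± 0.577 with sh3-2. HECTD2 and all other circRNAs at these counts were too rare to be tested in the fits above.

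By the authors' deposited p under 0.05 and a fold of at least 2, a rule taken up after the data were seen, these 3 were lower with both hairpins and 5 were higher with both. The higher ones had 0 control reads. Their folds are set against a floor of 3 control reads with the hairpin reads taken as exact, so they are not lower bounds. They came from the neddylation cofactor DCUN1D4 (4:52729603-52744020; 6.78-fold with sh3-1 and 2.38-fold with sh3-2) and the interferon gamma receptor chain IFNGR2 (21:34805457-34809991, intronic; 3.73-fold and 2.86-fold). The others came from the Rab regulator GDI2 (10:5836848-5842668; 2.71-fold and 11.0-fold), LYPLAL1 (1:219366424-219392054; 2.71-fold and 2.86-fold) and the fibrillin FBN2 (5:127854966-127866386; 2.03-fold and 7.14-fold). IFNGR2 reads with sh3-2 came from 1 library (6, 0 and 0), and GDI2 reads with sh3-1 also from 1 library (0, 0 and 8). Library A held most of the LYPLAL1 reads with sh3-2 (5, 0 and 1) and of the FBN2 reads with sh3-1 (5, 0 and 1). The bars of junction reads per library show these 8 circRNAs.

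**Figure D2:**
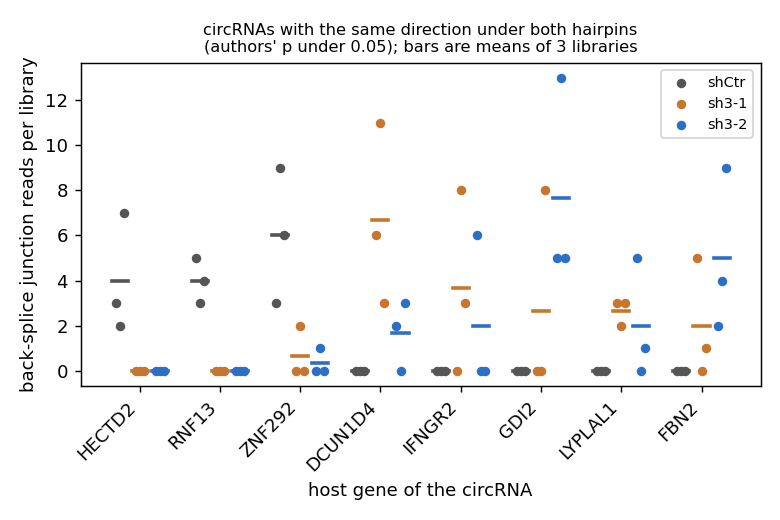
Junction reads per library of the 8 circRNAs that were lower or higher with both hairpins at the authors' p under 0.05 and a fold of at least 2. Points are the 3 libraries of shCtr, sh3-1 and sh3-2, and bars are their means.

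No circRNA was called with both hairpins. Among the 23 circRNAs tested with each, which include SPECC1, GUSBP1, MYH9 and HIPK3, log2 fold changes had a Pearson r of 0.39 (Spearman 0.38), against a median of 0.52 (0.20 to 0.77) in simulated unchanged libraries that share 3 simulated controls. The covariance was 0.0843 against a simulated 0.132 (0.0390 to 0.246), and 69.6% had the same sign against 68.3%. Unchanged libraries simulated against the 3 real controls, a setting added after the data were seen, gave a median r of 0.39 (−0.02 to 0.69), a covariance of 0.0763 and 62.7% of the same sign. Among the 4955 circRNAs in both tables, with no filter, r was 0.68 against 0.56 (0.55 to 0.58) the covariance 2.81 against 2.41 (2.32 to 2.58), and 81.5% had the same sign against 70.2%. Against the real controls simulated r was 0.57 (0.55 to 0.59), the covariance 2.38 to 2.58 and the share of the same sign 71.7%. Among these, circRNAs that passed by the authors' deposited p and fold numbered 12 and 18 among the higher and 45 and 22 among the lower ones, so separate lists would share 0.0436 and 0.200 by chance. At the same thresholds, a fit of all 9 libraries gave 7 higher and 3 lower with both, against simulated medians of 3 (1 to 7) and 14 (11 to 24). The 3 controls cannot be divided so that each hairpin keeps 2 of its own. Part of any excess over separate lists can therefore come from the shared controls, which gave overlaps in the unchanged simulated libraries too. The 3 lower circRNAs lay below the simulated range, while the unfiltered r lay above it. The simulated libraries thus do not settle whether the hairpins act alike.

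Between the hairpins, circles of KIAA0368 (9:114148657-114154104, log2 −1.15, SE 0.56) and ESYT2 (7:158552177-158557544, log2 −1.28, SE 0.65) lay lower with sh3-2 than with sh3-1. The SPECC1 circle lay higher (log2 0.48, SE 0.21). None passed, with an edgeR adjusted p of at least 0.477. Of 37 circRNAs tested (15.4% of junction reads), 21 were higher and 16 lower with sh3-2. EdgeR gave 0 calls, with 1 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 gave 0 calls with 2 at that level.

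Among host gene lists, only the hosts of often-described circRNAs had 5 tested members. With sh3-1, 4 of 11 were higher (ESYT2, CSNK1G3 and the ARHGAP5 circles) and 7 lower (XPO1, CAMSAP1, ZKSCAN1, FBXW7 −0.33, MAN1A2 −0.24, HIPK3 −0.24, RHOBTB3 −0.09), with a median log2 of −0.24 (camera adjusted p 0.443, 0.470 with an estimated correlation). Camera compares with the other tested circRNAs, and its direction was up with each hairpin, far from passing. The list's median nevertheless lay below the median of all tested circRNAs, which was −0.09 with each hairpin, so no lean is read from it. With sh3-2, 2 of 7 were higher (CSNK1G3 and HIPK3) and 5 lower (FBXW7, XPO1, MAN1A2 −0.13, RHOBTB3 −0.13, ZKSCAN1 −0.05), with a median of −0.13 (camera adjusted p 0.943). With reads summed per host, a setting added after the data were seen, the sign of the median turned with sh3-2 but not with sh3-1. For sh3-2, 8 of 12 were higher with a median log2 of 0.17 (camera adjusted p 0.409). For sh3-1, 6 of 13 were higher with a median log2 of −0.04 (camera adjusted p 0.245). Adjusted over the list alone, 0 members passed with either hairpin. Between the hairpins, 8 of 11 were higher with sh3-2 (median log2 0.21, camera adjusted p 0.620).

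The other lists are described by junction reads per 1000 in shCtr, sh3-1 and sh3-2. No difference passed (exact permutation, adjusted p 1), but none could, since the smallest p for 3 against 3 libraries is 0.1. This outcome was fixed in advance, so no conclusion for or against a difference is drawn from it. Hosts of HECT-domain ligases had 12.5 ± 3.53, 9.82 ± 2.37 and 10.2 ± 2.61, and factors of circRNA biogenesis and turnover had 4.42 ± 1.35, 2.49 ± 1.53 and 2.85 ± 0.899. Receptor kinase, PI3K and MAPK hosts had 11.2 ± 1.35, 8.52 ± 1.61 and 9.03 ± 3.46. TGF-beta and SMAD hosts, among them SMAD2, had means of 6.29, 6.94 and 5.68, and m6A machinery hosts had 3.99 ± 1.12, 3.93 ± 0.379 and 4.25 ± 0.980. Cell cycle hosts had means of 10.6, 11.5 and 10.8, adhesion and matrix hosts 8.15 ± 1.58, 8.39 ± 1.65 and 7.94 ± 1.79, and chromatin hosts 22.5 ± 6.25, 21.1 ± 1.39 and 25.5 ± 5.66. Squamous and fibroblast hosts had fewer than 1 read per 1000, and immune hosts had 0 circRNAs.

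In MeRIP-seq of sh3-2 against shCtr, 3 of the 23 m6A sites on a circRNA of IGF2BP3 itself were lower and 1 was higher by the authors' deposited FDR. By sign, 10 of the 23 were higher and 13 lower, with a median log2 fold of −0.04 from the authors' deposited folds. Since these may not be corrected for input, less IGF2BP3 RNA could also give lower sites. Per the authors' deposited table, sites 7:23508022-23508520 and 7:23509222-23509760 on the IGF2BP3 circRNA 7:23416342-23509835 were lower by 2.58-fold and 2.82-fold (FDR 1.33e-07 and 1.42e-07). A site on HECTD2 (10:93221011-93221113) was lower by 2.02-fold with an FDR of 0.0796 in the authors' deposited table, which does not pass 0.05. SMAD2 (18:45423002-45423380, 1.83-fold, FDR 3.85e-07), the inhibitory SMAD6 (15:67003782-67004140, 2.06-fold, FDR 6.03e-07) and the death receptor TNFRSF21 (6:47253680-47254331, 2.03-fold, FDR 2.42e-07) also had lower sites in the authors' deposited table. Per the authors' deposited table, 1340 of 14885 entries passed an FDR of 0.05, 666 higher and 674 lower, on 850 circRNAs of 753 hosts, with a median fold of 1.61.

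The largest folds in the authors' deposited table were higher for STXBP3 (1:109341102-109341420, 120.3-fold), SAMD4A (104.2), ATP6V1E2 (88.0), the integrin ITGB8 (7:20397522-20397820, 64.7), ZNF248 (63.5), CCDC88A (61.6), PEAK1 (54.2), CHMP4A (52.9), TLN2 (52.8) and ANAPC7 (52.5). Lower ones in the authors' deposited table were on RFXANK (19:19307482-19307680, 96.1-fold), KIAA1468 (72.8), CASP8AP2 (70.5), PHACTR4 (67.6), LRIG2 (67.3), RP11-381K20.2 (65.1), CEP350 (63.3), CUX1 (59.9), FIRRE (55.5) and FANCB (51.8). How these folds were computed is not given in the sources used here. None of these 20 sites lies on an exonic circRNA, while exonic circRNAs hold 5940 sites (40.6%).

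Factors of circRNA biogenesis and turnover had lower m6A sites when circRNAs were taken as units. The median log2 fold was −0.34 over 14 circRNAs of 7 hosts against −0.01 for circRNAs of other hosts (two-sided permutation, adjusted p 0.0346 over 9 lists). ADARB1 alone gave 6 of the 14, which the test takes as separate units. By the authors' deposited FDR 13 sites of the list were lower and 1 higher (18 and 3 adjusted over the list alone). The lower sites included those of the RNA-editing enzyme ADARB1 (9 sites; 21:46555242-46555620, 1.65-fold, FDR 1.97e-05 in the authors' deposited table), the splicing regulator QKI (1) and AGO2 (1). The higher one was on TNRC6B, which acts with AGO2 in microRNA silencing (2.82-fold, FDR 0.0134 in the authors' deposited table). Counted per host, over 7 hosts, the median log2 fold was −0.46 against −0.01 for other hosts, and the list did not pass (permutation, adjusted p 0.0895).

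Adhesion, matrix and EMT hosts had 7 higher and 0 lower sites by the authors' deposited FDR (8 and 1 adjusted over the list alone), from FAT1 (2), LAMB1 (2), COL12A1, ITGB8 and the focal adhesion kinase PTK2 (1 each). Their median log2 fold was 0.17 (permutation, adjusted p 0.0846). Cell cycle hosts had 13 higher and 3 lower (19 and 3 adjusted over the list alone), with 4 higher on the proliferation marker MKI67 and 3 on the centromere motor CENPE, but their median log2 fold over circRNAs did not pass (permutation, adjusted p 0.852). TGF-beta and SMAD hosts had 4 higher and 6 lower (6 and 8 adjusted over the list alone; permutation, adjusted p 0.852). SMAD6 (3), SMAD2 (2) and the SMAD corepressor SKIL (1) were lower, and TGFBR2 (2), SMAD5 (1) and TAB3 (1) higher. The remaining lists did not pass (permutation, adjusted p at least 0.152). Higher and lower sites numbered 5 and 5 for m6A machinery (5 and 5 adjusted over the list alone; ZC3H13 had 3 higher), 13 and 12 for often-described hosts (ERC1 had 4 higher) and 16 and 12 for chromatin hosts (KMT2C had 5 higher and SMARCC1 had 3 lower). Receptor kinase hosts had 1 and 3, and HECT-domain hosts 0 and 0. Squamous hosts (PKP4 with 3 of them) and fibroblast hosts (COL5A1) each had 4 higher and 0 lower sites (6 and 0 adjusted over the list alone), on too few circRNAs to test. By class, 50.7% of passing sites on exonic circRNAs were lower, and class did not pass as a difference (Fisher's exact p = 0.826).

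HECTD2 was the only circRNA lower with both hairpins and lower in m6A, by the authors' deposited p under 0.05 and a fold of at least 2 in each table. Of 1555 circRNAs in all tables, 2 were lower with both hairpins and 131 lower in m6A by that rule (exact one-sided hypergeometric p = 0.161). At an FDR of 0.05 there were 0, with 212 lower in m6A and 0 lower with both hairpins. Matched by host, RNF13 was added, with its lower site (3:149612982-149613180, 2.40-fold, FDR 0.0153 in the authors' deposited table) on another circle, 3:149540305-149639014. Log2 fold changes of circRNAs and of their m6A sites with sh3-2 had a Pearson r of −0.28 over the 7 circRNAs with both values (exact permutation p = 0.545). The sign turned without shCtr A (0.18), shCtr C, sh3-2 A or sh3-2 B, while the Spearman correlation (−0.32) stayed negative without each library. With no filter, a setting added after the data were seen, r was 0.070 over 2153 circRNAs (permutation p = 0.00110), and by the authors' deposited folds 0.071 (permutation p = 0.000770), with circRNAs as units.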

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

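The tests of the library pairs and the splits of libraries were chosen only after the result was seen, and those of the control-only circRNAs, the sh3-2 depth and the m6A sites were written down before.

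Mitochondrial back-splice junctions, which the series' text does not describe, held 0.185 ± 0.105% of junction reads in controls (mean ± SD, n = 3), 0.609 ± 0.397% with sh3-1 (exact two-sided permutation p = 0.2) and 1.10 ± 0.147% with sh3-2 (exact p = 0.1). They came from 41 junctions, 21 of them found in 1 library only, and the largest held 8.66% of the hairpins' mitochondrial reads. Reads summed over each of 24 chromosomes were also tested, which was not among the planned tests. The mitochondrial sum was higher with sh3-2 (log2 2.54, SE 0.43, edgeR adjusted p 1.27e-06). With sh3-1 it did not pass (log2 1.71, SE 0.84, edgeR adjusted p 0.343). The p-value with sh3-2 does not allow for the unplanned choice of test. It also takes sh3-2 B and C, which share many circRNAs, as separate libraries. Of the 10 ways to split the 6 libraries, 2 gave as many calls as the real split with sh3-2 (1 call; highest other 1), and 10 did with sh3-1 (0 calls; highest other 0). For circRNA calls, each of the 10 splits gave at least the 0 of the real one with sh3-1 (highest other 0), all 10 with sh3-2 (highest other 0) and all 10 between the hairpins (highest other 2). Where the real split gave 0 calls, this outcome was fixed in advance and tells nothing. A count of 10 splits is too small for a share under 0.05.

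The pairs sh3-1 A with B and sh3-2 B with C, which share 360 and 197 circRNAs found in no other library, were weighed against 4 explanations. A difference in depth was argued against, since the highest number in any other pair was 87. The hairpin itself was argued against as well, since the third library of a group shared at most 31 with one of the pair alone. Reads passing from one library to another at a low rate could not be told from the rest: on circRNAs of a pair alone with at least 3 reads in one library, the other held up to 10.7% as many reads for sh3-2 and up to 19.2% for sh3-1, against at most 4.18% in other pairs. The same starting RNA or library material in both libraries of the pair could not be judged either, since 0 labels record the RNA sample or culture of a library.

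The HECTD2 and RNF13 circRNAs and a circle of MCTP1 (5:94204038-94248681; 1, 1 and 8 control reads) were the 3 circRNAs with at least 10 control reads, reads in each control library and 0 in both hairpin groups. Sampling of rare junctions was tested with all 84 trios of libraries: 9 trios held at least 3 such circRNAs of their own (10.7%; highest other 7, the sh3-1 trio). Without the trios that hold a sharing pair, 5 of 70 (7.14%) did. The number is therefore consistent with sampling of rare junctions, and a loss of these circles with IGF2BP3 knockdown was not tested apart from it. The test concerns the number of such circRNAs and not HECTD2 alone.

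The m6A sites on circRNAs, such as those of IGF2BP3, SMAD2 and ADARB1, may lie on fragments of the linear host transcripts. This explanation was taken beforehand to predict that an exonic circRNA with more junction reads is no more likely to carry a site. A site was listed for 26.3% of exonic circRNAs with 2 reads in control and sh3-2 libraries. For those with 10 or more it was 27.8%, a ratio of 1.06, as predicted. Of all circRNAs with a site, 1178 (35.4%) had no junction read in these libraries. The test cannot tell linear fragments from sites on circles, since levels of the linear hosts, which may affect both, were not analysed here. No biological explanation of the site differences was tested.

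Junction reads were fewer with sh3-2. An even loss over circRNAs, which both a lower yield and a general fall of circRNAs would give, predicts as many circRNAs as in controls thinned to the same depth. The number of sh3-2 libraries outside that range, widened by 10%, was 0 of 3. Before the widening, sh3-2 A (1484 circRNAs) and B (1495) lay below the lowest thinned control (1608 and 1595), and C (1746) lay within its range, so the even loss rests on the margin.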

How the results depend on the processing

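Alternatives described as added were chosen only after the data were seen. Of the counts and correlations under planned and added settings, 45 stayed the same, 14 moved, 2 reversed and 1 was stronger. With a library left out, 40 stayed, 1 moved and 4 reversed. A count of 0 under both settings is among those that stayed. Such zeros are likely where few circRNAs can be tested, so this tally is not read as a measure of robustness. At an unadjusted p under 0.05 and a fold of at least 2 there were 2 calls with sh3-1, 1 with sh3-2 and 2 between the hairpins, where the chosen test gave 0 each. With no filter at that threshold (added) there were 39 and 61, and by the authors' deposited p and fold (added) 72 and 45, of which 8 had the same direction with both hairpins; these settings differ in threshold, and those with no filter or from the authors also in the circRNAs tested. Between the hairpins, calls numbered 1 with a replicate block and 0 to 1 with a library left out (1 without sh3-2 A); the cause was not tested. Letters did not pair, since 3 of 9 libraries correlated best with their own letter. By sign over all circRNAs, class with sh3-2 gave Fisher's exact p = 0.00522, with circRNAs and not libraries as units. In m6A, 2839 entries had an authors' deposited p under 0.05, and 822 also a fold of at least 2. Per host gene, 0 lists passed in m6A in place of 1, with fewer units tested. The correlation of circRNA and m6A folds was 0.070 with no filter (added; permutation p = 0.00110), 0.071 (permutation p = 0.000770) by the authors' deposited values, and −0.29 to 0.18 with a library left out (0.18 without shCtr A), in place of −0.28; the cause of the changed sign was not tested. CircRNAs lower in both datasets numbered 1 by the authors' deposited p and fold and 2 by host (added). The 40 named circRNAs had 546 values under the alternatives: 316 kept their direction and 1 reversed, and with a library left out 219 kept it and 10 reversed. The smallest adjusted p of any was 0.0998. Ranges of log2 fold change with a library left out crossed 0 for GUSBP1 (−1.12 to 0.074, the last without sh3-1 C) and ZKSCAN1 (−0.53 to 0.16, the last without shCtr C) with sh3-1. With sh3-2 they did for RARS (−0.077 without shCtr C, to 0.62), RNF13 (−0.070 without shCtr B, to 0.52), RBM33 (−0.066 without shCtr B, to 0.26), PRKD3 (−0.47 without sh3-2 B, to 0.59), PLOD2 (−0.29, to 0.22 without shCtr A) and LINC01004 (−0.98, to 0.33 without sh3-2 C, and 0.093 with the sharing pair summed, which was added). The cause was not tested. Only 33 and 24 circRNAs had the depth to be tested. A pseudocount does not apply to counts, and refits, a block and leaving out libraries were not run for m6A, which has no values per library.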

Other observations

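Host sums, and the hosts named here, were chosen only after the result was seen.

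Summed over all circles of a host gene, SFMBT2, a Polycomb protein gene with 8 circRNAs, had 16.3 ± 2.52 junction reads per control library (mean ± SD, n = 3), 5 ± 4.36 with sh3-1 (log2 −1.64, SE 0.71) and 3.33 ± 1.53 with sh3-2 (log2 −1.78, SE 0.70, edgeR adjusted p 0.293). The scaffold gene ERBB2IP had 16.7 ± 0.577, 14.3 ± 1.53 and 3.67 ± 1.53 reads (log2 −1.67, SE 0.67, edgeR adjusted p 0.293 with sh3-2). The 3 circles of GDI2 (log2 1.33) and the 8 of MGA (0.72) together lay higher with sh3-2. The smallest adjusted p over hosts with sh3-2 was that of MYH9 (log2 1.38, SE 0.38, edgeR adjusted p 0.0565), whose only circle is the one described above, so nothing was summed there. With sh3-1, the leukaemia inhibitory factor receptor LIFR (5 ± 3.46 reads against 16.7 ± 8.96) lay lower. The centrosome gene CEP192 (27.3 ± 6.66 against 14.3 ± 0.577) and ATXN10 (22.7 ± 3.79 against 11.3 ± 4.73) lay higher. Of 82 and 58 hosts, edgeR gave 0 calls with each hairpin, with 6 and 5 at an unadjusted p under 0.05.

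In m6A, an SFMBT2 site (10:7344002-7344200) was lower by 3.41-fold with sh3-2 (FDR 2.18e-08 in the authors' deposited table). On another SFMBT2 circle, in the authors' deposited table, one site was higher by 5.67-fold (10:7413642-7414060) and others were lower by 7.83-fold (10:7418302-7418680) and 1.66-fold (10:7412222-7412600). On the IGF2BP3 circle a further site, 7:23492422-23492660, was higher by 4.82-fold (FDR 0.0393 in the authors' deposited table). The 5 IGF2BP3 circRNAs had too few junction reads for a test, and no linear IGF2BP3 RNA was analysed here, so the knockdown was not checked.

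In sh3-1 libraries alone, 7 circRNAs had at least 10 reads with reads in each library. Libraries A and B of this group share 360 circRNAs found in no other library, which can raise this number. The highest mixed trios, which also hold sh3-1 A and B, had 4 such circRNAs. The 7 are therefore not read as an effect of the hairpin. These circRNAs came from PIAS2, PHACTR4, ATXN10, CCDC138, GMPS, ZNF131 and GTF2IRD1, with the most for ZNF131 (4.67 ± 2.08 reads). A further 5, from PPIP5K1, CAMKMT, PIK3CA, KIF14 and DST, had at least 10 reads in the library sh3-1 A and 0 in the other 8.

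All 20 of the largest m6A folds in the authors' deposited table are whole multiples of 0.1 in the digits deposited (no tolerance beyond computer rounding), as are 79 of the 81 passing sites with a fold of at least 20 and 1.86% of all sites. How a fold was computed where a group has few or no reads is not given in the sources used here, so the size and rank of the largest folds are left open.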
